A study of Mus musculus with 6 samples.

How the data were processed

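Extracellular vesicle RNA of mouse PBMCs was extracted with the exoRNeasy Maxi kit and made into libraries with the NEBNext Multiplex Small RNA kit, per the labels' protocols. CASAVA 1.8 and Bowtie are named in the submitters' processing notes, without a Bowtie version or a role for either. The genome build, the miRBase release, the caller of the unnamed miRNAs, the filters and the use of strand in counting are not given in the sources used here. The authors deposited 1 table with 620 miRNAs, 587 with a miRBase-style name and 33 numbered as predicted, and 2 values for each of the 6 libraries. The first is a read count, per the file headers. The second is headed TPM in the deposited table and equals the count divided by the library total times 1000000, with a largest difference of 4.8e-10, so no length enters it and it is called CPM here. Each library had 1 column of counts and 1 of TPM, and replicates were not pooled.

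Library totals ran from 125731 to 435468 counts, so 1 count was worth 2.30 to 7.95 CPM and the floor of 3 counts 6.89 to 23.9 CPM. The reads carry no molecular identifiers, so such floors cover counting error only. Groups and replicate numbers came from the library names in the labels, and the labels give no batch or date.

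The main test was the edgeR quasi-likelihood F test on the deposited counts with TMM factors and the filterByExpr filter (minimum count 10, minimum total 15), group as the only term, IS minus control, and a Benjamini-Hochberg adjusted p under 0.05. The filter left 206 miRNAs with 99.7% of the counts and removed 414, the 33 predicted ones included. The SE of a log2 fold change was its size divided by the square root of F. The 15 miRNA lists were tested with limma's camera at a preset correlation of 0.01 where 3 or more members were tested. Single values were compared with exact permutation tests over the 10 splits of the libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

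The groups, the tests, the lists, the naming rule and the alternatives were chosen before the data were examined, apart from those named as added. The rule named both arms of miR-744, the 12 miRNAs with the largest positive and the 12 with the largest negative fold among those past the threshold with separated groups, the miRNAs of smallest p up to 10 where fewer than 10 passed, the 10 most abundant miRNAs, and up to 3 of the most abundant tested members of each list. The alternatives were RLE factors, library totals alone, no filter, a filter of 10 CPM in 3 libraries, a replicate block, each library left out, DESeq2, limma on the log2 of the deposited TPM plus 1 or 0.5, other thresholds, an estimated correlation, fry, a detection limit of 5 counts, thinning to the smallest total, the 5 or 20 most abundant miRNAs, and other correlation settings. Leaving out repeated rows, with the preset and with an estimated correlation, and leaving out each library with the filter and scaling of all 6 kept, were added after the data were seen.

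Repeated rows were those whose counts differed by at most 2 counts or 6% in every library, with a total of 50 or more. There were 13 such pairs, 7 of them identical, and the 12 surplus rows took 10.0 to 19.0% of the library totals. Hairpin positions were looked up by name in the GENCODE annotation of GRCm38, which need not be the build the authors used. The 7 pairs looked up there are hairpins annotated on opposite strands of 1 place. They are not the same 7 as the identical pairs, since they include miR-24-3p with miR-3074-5p, whose counts differ slightly.

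The scripts were tested on simulated data, with counts drawn from the mean of each of the 620 miRNAs, the library totals and the observed spread, and with 200 miRNAs changed in each of 20 simulations. The median fold recovered was 1.00, 1.90, 3.04 and 3.96 for true log2 changes of 1, 2, 3 and 4, and 4.29, 32.2, 73.1 and 94.7% of the changed miRNAs tested were called. With a dispersion of 0.02, 90.4% were called at a log2 of 1. In 20 simulations with no change, 0 called a miRNA and 2 called a list. A muscle list raised by a log2 of 2 was called in 20 of 20. Every row was drawn independently there, so repeated rows did not share counts, and every muscle member was raised. How often lists are called in data with repeated rows was therefore not simulated.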

Results

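According to the labels, small RNA was sequenced from extracellular vesicles of mouse peripheral blood mononuclear cells (PBMCs), the lymphocytes and monocytes of blood. Such vesicles are membrane-bound particles that carry proteins and RNA out of the cell, microRNAs (miRNAs) among them. The 6 libraries formed 2 groups, with 3 from the vesicles of untreated cells (control) and 3 from vesicles labelled as stimulated with IS, an abbreviation that the labels do not spell out. The title of the series names salvianolic acid B, a plant compound, together with miR-744-5p and the heart disease of uremia. None of the 6 libraries is labelled as treated with salvianolic acid B. The total miRNA count was 270335, 235233 and 435468 in control libraries 1 to 3, and 149202, 317323 and 125731 in IS libraries 1 to 3. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

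A small set of miRNAs took most of the counts in both groups. The most abundant was let-7i-5p, of the let-7 family of differentiation-associated miRNAs, at 130377 ± 8706 CPM (counts scaled to a library total of 1000000) in control and 130760 ± 36851 CPM in IS (mean ± SD, n = 3 per group). It was followed by miR-148a-3p (124410 ± 46123 against 116393 ± 64176 CPM) and by the red cell miRNA miR-451a (87819 ± 31945 against 109142 ± 28812 CPM). The liver miRNA miR-122-5p stood at 60646 ± 46327 CPM in control and 57314 ± 43055 CPM in IS, and the same reads appeared a second time under miR-122b-3p. The list of the 10 most abundant was completed by miR-486a-5p, miR-486a-3p and miR-486b-3p, which are red cell miRNAs with nearly identical counts, and by let-7f-5p and miR-26a-5p. Red cell and liver miRNAs were thus among the most abundant in vesicles labelled as from PBMCs, and the source of these reads was not tested.

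These 10 miRNAs took 68.5 ± 4.02% of the counts in control and 71.3 ± 3.14% in IS (n = 3 per group, exact two-sided permutation p = 0.4). Between 276 (IS 1) and 513 (control 3) miRNAs had 1 or more counts, and the mean of the IS libraries lay 31 miRNAs below that of the control libraries (SD 125 in control and 89.8 in IS, exact permutation p = 0.6). Without control 3, which was the deepest library, IS minus control turned from -31 to 41, and with every library thinned to 125731 counts it was -13.3, control 3 still having the most (412). For the total counts the exact permutation test gave p = 0.3. With 3 libraries against 3, the smallest two-sided p such a test allows is 0.1.

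Which vesicle miRNAs differed after IS stimulation was the question of the main comparison, and no single miRNA passed its threshold. The smallest unadjusted p belonged to miR-1a-3p, a miRNA of heart and skeletal muscle, at 299.2 ± 127.2 CPM in control and 925 ± 492 CPM in IS (log2 fold change 1.68, SE 0.62, adjusted p = 0.996, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Also among the 10 of smallest p was miR-744-5p, the miRNA named in the series title, with a log2 fold change of -2.06 (SE 0.93) that was -0.31 without control 2, or -0.036 with the scaling of all 6 libraries kept. The lymphocyte miRNA miR-181d-5p had 75.7 ± 35.8 CPM in control and 206 ± 34.3 CPM in IS. For miR-574-5p the values were 182 ± 35.2 CPM and 72.2 ± 8.40 CPM. In both of these, the 3 IS values lay outside the range of the 3 control values.

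Of the 206 miRNAs tested with edgeR, 0 passed an adjusted p of 0.05, and 3 had an unadjusted p under 0.05 (smallest 0.020), where 10.3 would be expected by chance. DESeq2 also called 0, of 618 miRNAs, with 14 at an unadjusted p under 0.05 and 30.9 expected. It was run without the filter, and miRNAs with very few counts can hardly reach such a p, so 30.9 is too high. The separation of the 2 groups seen for miR-181d-5p and miR-574-5p occurred in 3 of the 206 tested miRNAs (1.46%, where chance gives 10%). The other was miR-140-3p, which is named because the count is small and not by the naming rule. These chance values take the libraries as independent. In edgeR the other splits of the libraries gave from 2 to 29 miRNAs at an unadjusted p under 0.05. The spread within groups was wide, with a biological coefficient of variation of 68.1% and a median 95% confidence interval of 1.68 on either side of a log2 fold change. In data simulated with this spread, the same test called 32.2% of tested miRNAs changed by a log2 of 2, 73.1% at 3 and 94.7% at 4. There 200 of 620 miRNAs were changed at once, and the libraries were drawn independently. With only a few changed the adjustment is stricter, and the share called was not simulated.

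None of the 10 miRNAs of smallest unadjusted p was past the threshold. The counts of miR-1b-5p were identical to those of miR-1a-3p in every library, so the 2 names stand for 1 set of reads. The third muscle miRNA among them, miR-206-3p, had 729 ± 1008 CPM in control and 1793 ± 1476 CPM in IS (log2 fold change 1.55, SE 1.02), and its log2 fold change was 0.21 without IS 1 and 3.31 without control 2 (0.42 and 3.75 with the scaling of all 6 libraries kept). For miR-99b-5p the log2 fold change was -1.54 (SE 0.72) and for let-7e-5p it was -1.30 (SE 0.76). The hairpins of these 2 miRNAs are neighbours in an intron of Spaca6 on chromosome 17, at 17830188 to 17830257 for Mir99b and 17830352 to 17830444 for Mirlet7e (plus strand, GRCm38). The log2 fold change of miR-24-3p was -0.76 (SE 0.46), and the nearly identical counts of miR-3074-5p gave the same value. The Mir181d hairpin lies in an annotated intron of Nanos3 on chromosome 8 (84178716 to 84178787, minus strand), and that of Mir574 in an intron of Fam114a1 on chromosome 5 (64970318 to 64970395, plus strand).

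**Figure D1:**
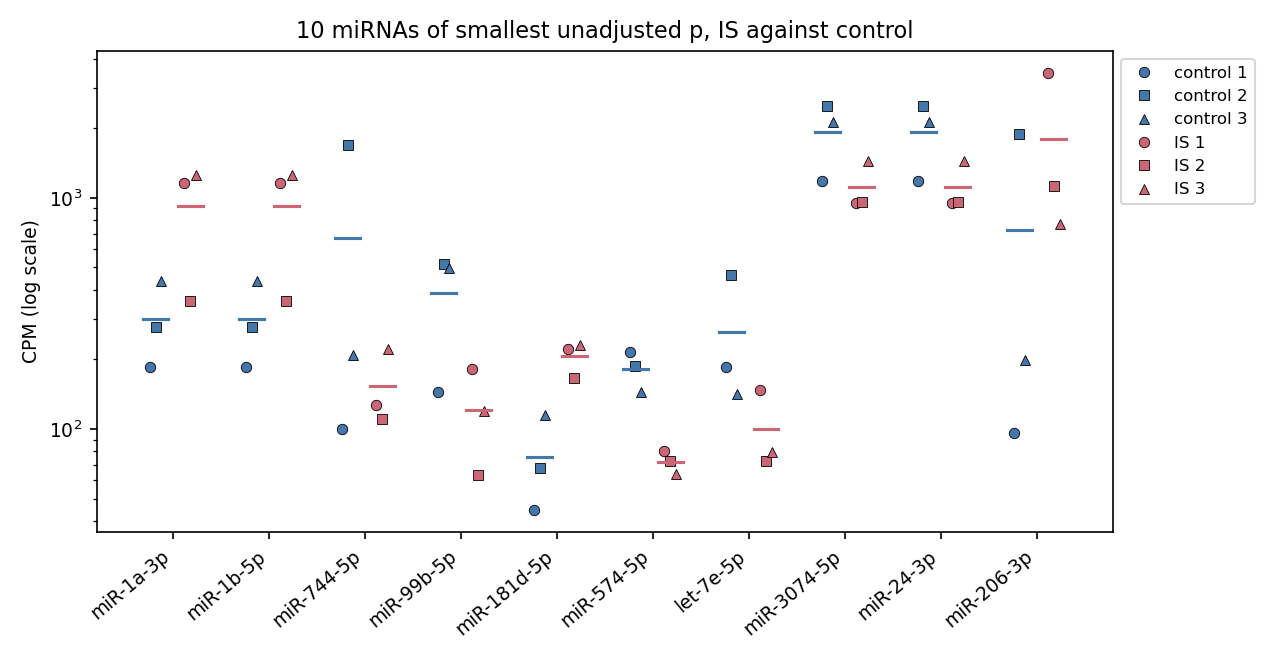
CPM on a log scale of the 10 miRNAs of smallest unadjusted p, with 1 point per library, control in blue, IS in red and a bar at each group mean. The miR-744-5p value of control 2 (1696 CPM) stands above the other 5 libraries (99.9 to 223 CPM), while the groups do not overlap for miR-181d-5p and miR-574-5p.

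The difference in miR-744-5p rested on 1 control library. It was 99.9, 1696 and 209 CPM in control 1, 2 and 3 (27, 399 and 91 counts) and 127.3, 110.3 and 223 CPM in IS 1, 2 and 3 (19, 35 and 28 counts). The group means were 668.3 ± 892 and 153 ± 60.6 CPM (n = 3 per group), and the exact two-sided permutation test gave p = 0.7. In the edgeR quasi-likelihood fit the log2 fold change of -2.06 had an unadjusted p of 0.049 and an adjusted p of 0.996. Without control 2 it was -0.31 (SE 0.89), or -0.036 (SE 0.83) with the scaling of all 6 libraries kept. The series title names this miRNA, so its place among the smallest p-values is not independent evidence of a direction. The opposite arm of the hairpin, miR-744-3p, had 2 counts in control 3, 2 counts in IS 3 and 0 in the other libraries, under the floor of 3 counts, and no fold is given. The Mir744 hairpin lies in an intron of Map2k4 on chromosome 11 (65734733 to 65734832, minus strand, GRCm38).

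Groups of miRNAs fixed by cell type, family or genomic cluster were compared to see whether any moved together, and 1 of the 13 tested groups passed the threshold. The heart and skeletal muscle miRNAs had a median log2 fold change of 0.92 over 6 tested members (camera, preset correlation of 0.01, adjusted p = 0.015), with its highest values in miR-1a-3p, its repeat miR-1b-5p, and miR-206-3p. With an estimated correlation the adjusted p of the list was 0.498 at the same median, and with the repeated rows left out it was 0.126 (median 0.28). An estimated correlation leaves camera far fewer degrees of freedom, so its p can rise without any correlation. The values of the remaining members lay nearer to 0: miR-133a-3p, transcribed with miR-1a in muscle, had a log2 fold change of 0.28 (SE 1.04), miR-499-5p, encoded in a myosin gene, had -0.10 (SE 0.82), and miR-378a-3p had -0.06 (SE 0.58), which turned to 0.03 under RLE scaling. Of the 6 members, 0 passed the threshold over all miRNAs and 0 when adjusted over the list alone. The adjusted p of the list was 0.332 without control 1 (median 0.12), 0.202 without IS 1 (0.23), 0.104 without IS 2 (1.01) and 0.060 without IS 3 (0.78), and with the scaling kept the medians were 0.54, 0.39, 1.05 and 1.16.

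Of the other 12 tested lists, 11 had a median that took the other sign when some library was left out, with the scaling refitted or kept. Among miRNAs of blood cells, the erythroid list had a median log2 fold change of 0.40, which was -0.041 without control 1 and -0.069 without IS 2 (7 members, camera adjusted p = 0.362). Its members took 16.8, 16.6 and 31.0% of the counts in control 1 to 3 and 19.3, 37.5 and 23.7% in IS 1 to 3, reads of miR-486 that were counted in 3 rows included. The lymphocyte list had a median of 0.53, which lay between -0.17 (without IS 3) and 0.40 with a library left out (7 members, adjusted p = 0.217), with miR-150-5p at 390 ± 393 CPM in control and 541.2 ± 506 CPM in IS, miR-342-5p at 164 ± 76.5 and 248 ± 185 CPM, and miR-181a-5p at 857 ± 286 and 823 ± 535 CPM. The platelet and endothelial list had a median of -0.17, which was -1.02 without IS 3, 0.10 without IS 2 and, with the scaling kept, 0.16 without control 1 (6 members, adjusted p = 0.519), and its vessel wall miRNA miR-126a-3p stood at 17563 ± 7898 CPM in control and 14801 ± 10797 CPM in IS. Another member, miR-191-5p, had a log2 fold change of -0.12 (SE 0.49). For the myeloid list the median was 0.18 (-0.87 without IS 3) and the mean 0.017, while the test pointed down (9 members, adjusted p = 0.718). Its most abundant members were miR-142a-5p (11725 ± 7718 against 13626 ± 9191 CPM), miR-23a-3p and miR-27a-3p.

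The inflammatory response list, with miR-21a-5p, miR-146a-5p and miR-146b-5p as its most abundant members, had a median of 0.28 (-0.31 without IS 2) and a mean of 0.032, and its test pointed down (7 members, adjusted p = 0.748). miR-21a-5p stood at 40660 ± 13455 CPM in control and 27968 ± 16772 CPM in IS (log2 fold change -0.57, SE 0.50, and -1.34 to -0.28 with a library left out), and miR-146a-5p, a brake on NF-kB signalling, at 3182 ± 1479 and 3685 ± 2351 CPM. The liver and epithelium list had a median of 0.40, which lay between -0.082 (without IS 3) and 0.66 with a library left out (7 members, unadjusted p = 0.024, camera adjusted p = 0.156), with miR-200a-3p at 0.51 (SE 0.73) and miR-192-5p at 0.04 (SE 0.49). The let-7 family had a median of -0.19, which lay between -0.44 and -0.00074 with a library left out (10 members, adjusted p = 0.217), the miR-29 and miR-30 families, linked to fibrosis, a median of -0.08 that turned to 0.011 under RLE scaling and to 0.21 without IS 3 with the scaling kept (7 members, adjusted p = 0.657), and the miR-17 to miR-92 cluster with its paralogues a median of -0.11, or 0.19 without control 1 with the scaling kept (8 members, adjusted p = 0.748). In these families let-7g-5p, miR-30e-5p and miR-106b-3p had log2 fold changes within 0.02 of 0, whose signs turned under another scaling. The values of miR-30a-5p, miR-92a-3p and miR-25-3p were -0.28, -0.40 and 0.12, each of the other sign with some library left out, and that of miR-30d-5p was -0.43 (-1.27 to 0.24 with a library left out).

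The fibroblast and smooth muscle list had a median of 0.016 that turned to -0.066 with library totals alone and to -0.59 without IS 1, a mean of -0.10 and a test that pointed down (4 members, adjusted p = 0.657), with miR-143-3p at 7753 ± 311 CPM in control and 7199 ± 2223 CPM in IS, miR-199a-3p at a log2 fold change of -0.63 (SE 0.59) and miR-199a-5p at 0.13 (SE 0.59). The neural list had a median of -0.015 that turned to 0.0054 under RLE scaling and to 0.30 without IS 2, a mean of 0.21 and a test that pointed up (3 members, miR-128-3p, miR-218-5p and miR-129-5p, adjusted p = 0.718). The imprinted Dlk1-Dio3 cluster, a large group of miRNAs expressed from the maternal chromosome, had a median of 0.05 over 25 members, or -0.024 with library totals alone and -0.61 without IS 3 (adjusted p = 0.718). Of the 25, 15 had a log2 fold change above 0, while the 3 most abundant, miR-381-3p, miR-409-3p and miR-370-3p, had -0.17, -0.26 and -0.74. Without control 2 the last 2 of these were 0.51 and 0.47 (0.83 and 0.67 with the scaling kept), the library behind the miR-744-5p difference, and without IS 2 miR-409-3p was 0.11. The p53 and senescence list and the Sfmbt2 intron cluster had 2 tested members each and no test, with medians of 0.28 (miR-22-3p and miR-146a-5p) and 0.26 (miR-466i-5p and miR-669c-5p). In all 15 lists, 0 members passed the edgeR threshold over all miRNAs and 0 when adjusted over the list alone. No list other than that of heart and skeletal muscle passed with camera, and none passed with an estimated correlation. The latter setting is much stricter for every list, as camera then has far fewer degrees of freedom.

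**Figure D2:**
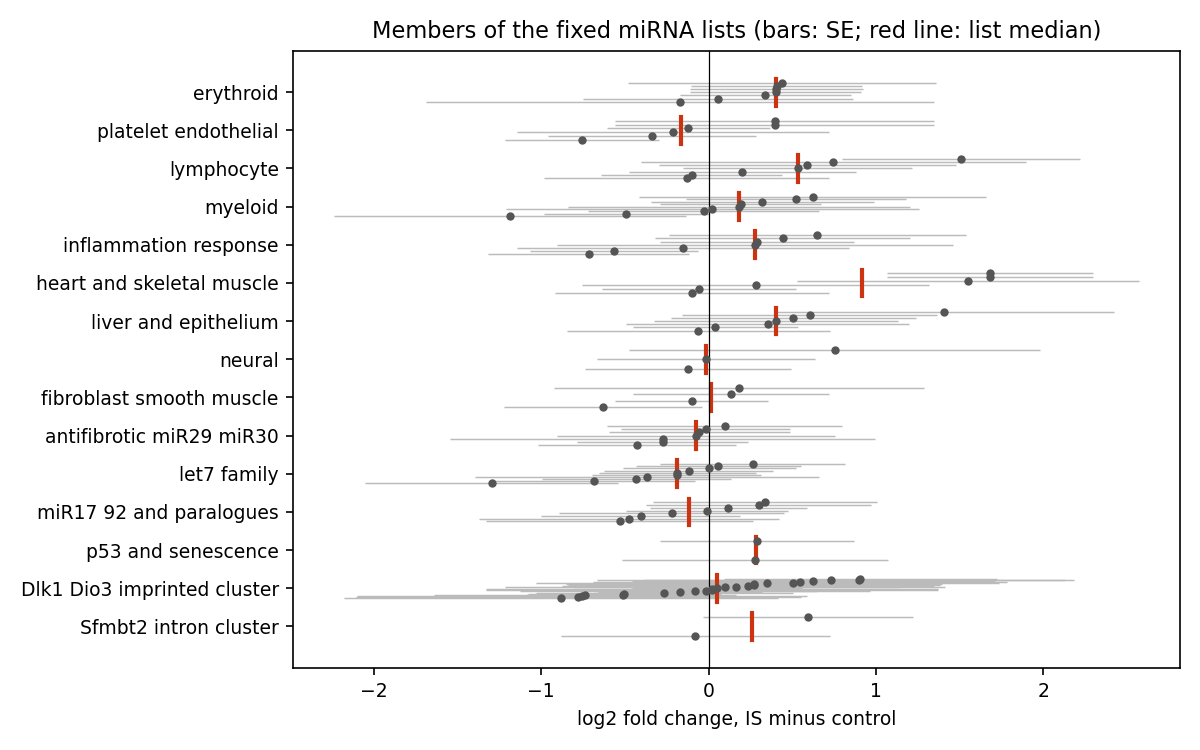
Log2 fold change (IS minus control) of every tested member of the 15 fixed lists, with 1 point per miRNA, grey bars for the SE and a red line at the list median. The heart and skeletal muscle list has the highest median (0.92), and its 3 highest points are miR-1a-3p, miR-1b-5p and miR-206-3p.

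Whether libraries of a group resembled each other more than libraries of different groups was read from correlations over all miRNAs. Control 3 and IS 2 were the most alike, sharing high miR-142a-5p (20128 and 23909 CPM) and miR-22-3p (5530 and 5874 CPM). The mean Pearson r of log2(CPM + 1) was 0.846 within groups and 0.857 between groups, a difference of -0.011 (exact one-sided permutation p = 1, for a higher r within groups). The real split had the lowest difference of the 10. Another split, with control 1, control 2 and IS 2 together, gave -0.0107, against -0.0111 for the real one. Each of the 6 libraries had its highest correlation with a library of the other group, where it has 3 candidates against 2 in its own. Over the 206 tested miRNAs 5 of the 6 did, control 1 lying nearest to control 3 (0.865, against 0.864 with IS 1). No 2 libraries were identical or agreed within sampling noise, the lowest chi-square per degree of freedom being 23.5, for control 1 and IS 1.

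**Figure D3:**
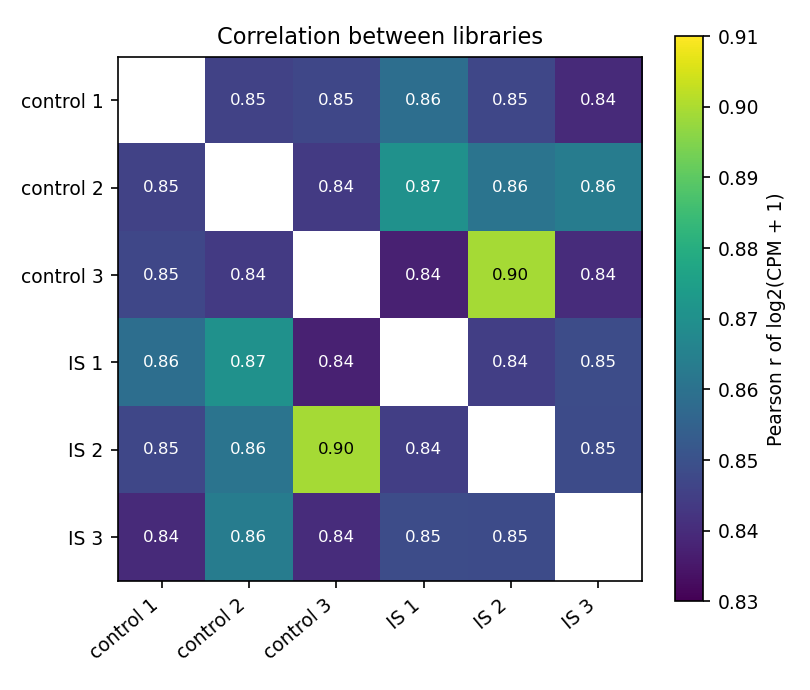
Pearson r of log2(CPM + 1) across miRNAs for each pair of the 6 libraries, coloured from low (dark) to high (yellow). The highest value, 0.899, joins control 3 and IS 2, and the lowest is 0.837.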

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

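The tests with repeated rows left out, with either correlation, and those with a library left out and the scaling kept, were chosen after the data had been seen, and the other alternatives were planned.

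The count of miRNAs past the edgeR threshold was 0 under every alternative that kept an adjusted p, with DESeq2 and limma as well, and 3 at an unadjusted p under 0.05. The log2 fold change of miR-744-5p kept its sign and stayed short of the threshold in all of them, from -2.92 (without control 1) to -0.31 (without control 2), or -0.036 with the scaling kept, and with -1.16 for limma on log2(TPM + 1). The count of lists past the threshold was 1 with RLE factors, library totals, no filter, the filter of 10 CPM and the replicate block, 0 with repeated rows left out, 0 with an estimated correlation (with or without repeated rows), 0 with directional fry (smallest adjusted p 0.627), 0 with mixed fry, and 0 to 1 with a library left out. Without control 2 or control 3 the muscle list passed (adjusted p 0.023 and 0.031, or 0.0268 and 0.0495 with the scaling kept), and with any 1 of the other 4 libraries left out no list did, with the scaling refitted or kept. Leaving a library out and refitting the filter and scaling moved the median log2 fold change of all tested miRNAs from 0.022 to between -0.27 and 0.050. With the filter and scaling kept it lay between -0.058 and 0.12. Part of the refitted values below therefore comes from the refitted filter or scaling, which were not told apart. Repeated rows hold the same reads under 2 names, so leaving them out removed 1 muscle member, and the cause of the other losses was not tested. With an estimated correlation camera also has far fewer degrees of freedom, so that setting does not test correlation alone. The difference in detected miRNAs ranged from -82.5 to 41 with a library left out, turning without control 3, the deepest library, and was -13.3 at equal totals. The share of the 10 most abundant miRNAs and the similarity of libraries kept their sign in every alternative, from 1.10 (without IS 1) to 5.10 percentage points (without control 1) and from -0.017 to -0.0055 with a library left out, against 2.80 and -0.011 with all. Equal replicate numbers showed no common pairing in the data, as the deviations from the group means correlated at 0.36, -0.41 and -0.17. With the replicate block 0 miRNAs and 1 list passed, miR-744-5p standing at -1.03 (SE 1.03). Not every library correlated best with its own number. The deviations of control 1 and IS 1, control 2 and IS 3, and control 3 and IS 2 correlated at 0.36, 0.36 and 0.58. No label gives this matching, which was seen in the data and entered no test. The SEs and p-values therefore do not allow for it. Deviations cancel out within a group, so the best matching tends to correlate above 0 by construction. By Pearson r of log2(CPM + 1), control 2 lay nearest to IS 1 over all miRNAs (0.871) and to IS 3 over the tested ones (0.862). Depth limits the miRNAs near 3 counts, and the spread between libraries limits the rest.

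Of the 52 other named miRNAs, 12 kept their sign in every alternative and 40 did not, in 171 of 1138 values, and none was past the threshold in any. Of the 13 tested lists, 8 changed direction in 31 of 285 values, and none of those 8 was called. The cause was not tested. With RLE factors the sign turned for miR-378a-3p (0.033), miR-128-3p (0.0054), miR-30e-5p (0.060) and miR-106b-3p (0.055). With library totals alone the sign turned for let-7g-5p (-0.027) and miR-669c-5p (0.041). Without the filter the sign turned for miR-378a-3p (0.026), miR-128-3p (0.012), miR-30e-5p (0.067) and miR-106b-3p (0.051). Without the filter camera's direction turned for the lists inflammatory response (median 0.29), miR-17 to miR-92 (median -0.12) and Dlk1-Dio3 (median -0.10). With 10 CPM or more in 3 libraries the sign turned for let-7g-5p (-0.039). With that filter camera's direction turned for the lists inflammatory response (median 0.22) and Dlk1-Dio3 (median -0.034). With the replicate block the sign turned for let-7i-5p (-0.0090), miR-128-3p (0.084), let-7g-5p (-0.040) and miR-409-3p (0.14). With repeated rows left out the sign turned for miR-128-3p (0.011) and miR-106b-3p (0.0011). With DESeq2 the sign turned for miR-122-5p (0.015), miR-122b-3p (0.015), miR-378a-3p (0.041), miR-128-3p (0.033), miR-30e-5p (0.073), miR-106b-3p (0.070) and miR-669c-5p (0.0089). With limma on log2(TPM + 1), with and without the filter, and on log2(TPM + 0.5), the sign turned for let-7i-5p (-0.030), miR-128-3p (0.024) and let-7g-5p (-0.042). Over the 12 fits with a library left out, with the scaling refitted or kept, the log2 fold changes were miR-1a-3p (1.10 to 2.06), miR-1b-5p (1.10 to 2.06), miR-99b-5p (-2.33 to -1.22), miR-181d-5p (0.95 to 1.85), miR-574-5p (-1.63 to -1.01), let-7e-5p (-2.01 to -0.72), miR-3074-5p (-1.28 to -0.58), miR-24-3p (-1.28 to -0.58), miR-206-3p (0.21 to 3.75), let-7i-5p (-0.27 to 0.31), miR-148a-3p (-0.72 to 0.28), miR-451a (-0.17 to 0.53) and miR-122-5p (-1.17 to 1.01). Next by name were miR-122b-3p (-1.17 to 1.01), miR-486a-5p (-0.082 to 0.74), let-7f-5p (-0.60 to 0.080), miR-486a-3p (-0.069 to 0.71), miR-486b-3p (-0.065 to 0.73), miR-26a-5p (-0.87 to 0.040), miR-126a-3p (-1.25 to 0.064), miR-191-5p (-0.48 to 0.14), miR-181a-5p (-0.77 to 0.20), miR-150-5p (-0.65 to 1.73), miR-342-5p (-0.38 to 0.90), miR-142a-5p (-0.43 to 0.82) and miR-23a-3p (-0.21 to 0.44). They were followed by miR-27a-3p (-0.98 to -0.26), miR-21a-5p (-1.34 to -0.28), miR-146a-5p (-0.45 to 0.61), miR-146b-5p (-1.53 to -0.063), miR-378a-3p (-0.78 to 0.46), miR-192-5p (-0.46 to 0.20), miR-200a-3p (-0.58 to 0.90), miR-128-3p (-0.73 to 0.37), miR-218-5p (-0.88 to 0.15), miR-129-5p (-0.18 to 2.07), miR-143-3p (-0.53 to 0.11), miR-199a-3p (-1.18 to 0.050) and miR-199a-5p (-0.43 to 0.39). The rest were miR-30d-5p (-1.27 to 0.24), miR-30e-5p (-0.57 to 0.27), miR-30a-5p (-0.75 to 0.046), let-7g-5p (-0.47 to 0.29), miR-25-3p (-0.32 to 0.35), miR-106b-3p (-0.38 to 0.28), miR-92a-3p (-0.97 to 0.35), miR-22-3p (-0.85 to 1.27), miR-381-3p (-0.59 to 0.073), miR-409-3p (-0.97 to 0.83), miR-370-3p (-2.32 to 0.67), miR-669c-5p (-1.12 to 0.42) and miR-466i-5p (-0.24 to 0.94). The list medians over these fits (11 for neural, as for miR-129-5p) were erythroid (-0.069 to 0.71), platelet and endothelial (-1.02 to 0.16), lymphocyte (-0.17 to 0.40), myeloid (-0.87 to 0.39), inflammatory response (-0.31 to 0.47), heart and skeletal muscle (0.12 to 1.21), liver and epithelium (-0.082 to 0.66), neural (-0.73 to 0.37), fibroblast and smooth muscle (-0.59 to 0.18), miR-29 and miR-30 (-0.59 to 0.21), let-7 (-0.44 to -0.00074), miR-17 to miR-92 (-0.45 to 0.19) and Dlk1-Dio3 (-0.61 to 0.20). In some alternative the medians of 11 of the 13 lists took the other sign.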

Other observations

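Leaving out control 2, the other scalings and the estimated correlation were listed before the data were seen, but these 3 tests were applied to an explanation only after the result was known, and the tests of the muscle markers, of repeated rows, with either correlation, and of a kept scaling were first chosen once the data had been seen.

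Single libraries differed in miRNAs that did not follow the groups. Control 3 and IS 2 had 19696 and 17730 CPM of miR-378a-3p, against 5751 to 8057 CPM in the other libraries, and 836 and 1094 CPM of the lymphocyte miRNA miR-150-5p, against 92.5 to 429 CPM. The same 2 libraries had the lowest miR-126a-3p, at 8928 and 4774 CPM, and the lowest miR-148a-3p, at 78688 and 43350 CPM. The liver miRNA miR-122-5p stood at 112546 CPM in control 1 and 107023 CPM in IS 1, against 23470 to 45923 CPM elsewhere. DESeq2 ranked miR-1197-3p of the Dlk1-Dio3 cluster first, at 0 CPM in the 3 control libraries and 60.3, 9.45 and 31.8 CPM in IS 1, 2 and 3, with a DESeq2 adjusted p of 0.9997. It was named after its values were seen.

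The libraries lay closer to the other group than to their own, but the 10 splits are too few to set this apart from chance. Unequal totals are argued against, since the difference of within and between stayed at -0.0114 (SD 0.0014 over 50 thinnings) at equal totals, and so are the repeated rows and the 10 most abundant miRNAs, without which it was -0.0124 (bootstrap SD 0.0048). An exchange of 1 control and 1 IS library may account for it and cannot be told apart from chance: the 9 other splits also gave 0 miRNAs past the threshold, and the bound set beforehand, no call in any of them, was inadequate because the test called 32.2% of miRNAs changed by a log2 of 2 in simulations. That was decided after the result. At an unadjusted p under 0.05 the real split gave 3 miRNAs and the highest other 29 (control 1, control 2 and IS 1 together). Each had 0 past the adjusted threshold, and no biological explanation was tested. The deviations of control 1 and IS 1, control 2 and IS 3, and control 3 and IS 2 correlated at 0.36, 0.36 and 0.58. The best matching tends to correlate above 0 by construction, as deviations cancel out within a group. A pairing of libraries across the groups cannot be told apart from an exchange, since no label gives it and it entered no test.

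The lower miR-744-5p in IS may come from 1 control library, since its log2 fold change was -0.31 (SE 0.89) without control 2, or -0.036 with the scaling kept, and at most -1.91 without any other single library (-1.90 with the scaling kept). For the size of the fold, scaling is argued against, the values being -2.05 (SE 0.94) with RLE factors and -2.13 (SE 0.98) with library totals against -2.06 (SE 0.93). For the crossing of 0.05 alone it is a candidate, since these larger SEs took the unadjusted edgeR p from 0.049 to 0.0517 and 0.0533. Other settings moved the p further: 0.0075 in edgeR with no filter, 0.026 with DESeq2 and 0.24 with limma on log2(TPM + 1). What set control 2 apart, in the cells or in the library, was not tested, and an effect of IS stays open.

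The higher muscle list may owe its place to reads counted under 2 names, miR-1a-3p and miR-1b-5p, since its adjusted p was 0.126 (median 0.28) with repeated rows left out. Correlation between members stays undecided, since the test made of it cannot decide. Once it was estimated, the adjusted p was 0.498 at an unchanged median of 0.92, but the estimate of 0.046 counts the 2 names as members. Without the repeat the estimate was -0.052, below the preset of 0.01. The camera p still rose there from 0.019 to 0.074 (adjusted 0.126 to 0.541). An estimated correlation leaves camera only the residual degrees of freedom of the 6 libraries, far fewer than the preset does. That raises p by itself, so a rise under this setting is no sign of correlation. RNA from muscle cannot be told apart from these explanations. The median log2 fold change of the other 3 members was -0.057 (SD 0.21), below the bound of 0.5. That bound was inadequate, as decided after the result, because miR-133a-3p and miR-499-5p had SEs of 1.04 and 0.82. The level of miR-378a-3p, at 5751 CPM or more in every library, would also hide a small share. An effect of IS on the cells stays open and was not tested apart from these.

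The 10 splits of the 6 libraries are too few for a share under 0.05. All 10 gave as many miRNAs past the threshold as the real one (0, highest other 0), and 3 of 10 gave as many lists (1, highest other 2).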
